A study of Homo sapiens with 183 samples.

How the data were processed

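Gene expression was measured on 183 two-colour Agilent oligonucleotide arrays in MCF-7 cells, a human breast cancer line that carries estrogen receptor alpha. Per the labels, the cells were deprived of steroids and then exposed to 1 of 20 compounds for 1, 4 or 48 h, RNA was extracted on columns, and amplified RNA was marked with Cy5 or Cy3 by T7 transcription. The labels name 121 treated extracts, 12 solvent control extracts (1 for each of 4 sets and 3 times) and a common reference RNA, which was on Cy5 in 36 arrays and on Cy3 in 35. The arrays formed 35 closed loops of 4 to 6 arrays (1 of 4, 25 of 5 and 9 of 6), in which each extract was measured with both dyes; the series text speaks of 12 loop designs.

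The deposited scanner files hold spot intensity on a linear scale for each dye, extracted per the file headers with Agilent Feature Extraction 8.5.1.1 for the 63 arrays of 48 h and 9.1.1.1 for the 120 arrays of 1 and 4 h, while the labels name 8.5.1.1 for all. They also hold a log10 ratio of Cy5 over Cy3 that, per the file headers, Agilent's software made from its background-subtracted and dye-normalised signals; it lay within 0.01 of the log10 ratio of the processed signals in 97.18% of spots. The series matrix deposited by the authors holds log2 ratios, whose scale and direction were not stated and were found by comparison with the scanner log ratios of the same array (r between 0.79 and 1.00 across spots, slope between 0.98 and 1.04). Its column medians lay between -0.02 and 0.11; how its authors centred the arrays and combined the 2 spots of a probe is not given in the sources used here. The matrix served only as an alternative.

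From the scanner intensities, the background was corrected with normexp (offset 50), the ratios were normalised within each array by loess with control spots at weight 0, and spots marked as outliers were left out. The 2 spots of a probe were averaged. A probe was kept when it was well above background in at least 5% of the channel measurements, which left 5095 of 5114 probes and 4593 of 4609 gene names. Of the probes, 4618 were named through their accession in the reference table of gene names, 347 through a matched file name, and 149 kept the name in the file. For the 501 genes with more than 1 kept probe the brightest probe was used, and disagreeing probes are given beside the gene. The share of spots well above background was 82.1% to 99.3% per array and channel (median 90.2%), and the median signal was 173.7 to 768.4 for Cy5 and 197.3 to 609.4 for Cy3. No file repeated the signals of another (0 pairs).

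Levels were estimated in 2 steps. The log2 ratios of the arrays were regressed on the RNA extracts plus a dye term, which gave each extract's level relative to the common reference (median residual SD 0.090 per array); arrays of the same extract thereby counted once. In the second step, limma fitted 1 mean per compound and time and 1 per control to all extracts, which shared an estimate of the spread (61 residual degrees of freedom, 3.90 prior degrees of freedom, median SD 0.081). Each compound's mean over its concentrations was compared with the solvent control of its own set and time by the moderated test, adjusted by Benjamini-Hochberg over genes at a threshold of 0.05. No concentration and time had more than 1 extract, so concentrations served as replicates, and real differences between concentrations widen the estimated spread. The labels do not say that extracts came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision.

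Sets of genes were fixed before the data were examined, from general knowledge: estrogen-induced (17 genes tested), estrogen-repressed (8), cell cycle (27), immediate early (18), aryl hydrocarbon receptor (6), p53 targets (15), NRF2 targets (10), endoplasmic reticulum stress (8), sterol synthesis (12), androgen-induced (1), thyroid hormone-induced (3), and markers of stromal and immune cells (5). Each list was set against all other genes with limma's cameraPR at a preset inter-gene correlation of 0.01, adjusted over the 11 lists of more than 1 gene within a compound or, where stated, over the 20 compounds; the alternative correlation was estimated from the residuals of the fit. Those residuals are differences between concentrations of a compound, so responses to concentration that a list's genes share can raise the estimated correlation. It was 0.50 for the estrogen-induced list and 0.73 for the cell cycle list. The error of a list's mean was obtained by treating that mean as 1 number per extract, and intervals are 95% intervals. The genes named were also chosen by a rule fixed beforehand. For 17beta-estradiol at each time they were the 10 largest rises and 10 largest falls past the threshold with the same direction at every concentration. For the 4 aryl hydrocarbon receptor ligands at 48 h the 8 largest rises and 5 largest falls with the same direction in all 4 compounds, and for each other compound at 48 h the 2 largest rises and the largest fall. Any member of a fixed list could also be named. Genes outside this rule are named as such.

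The procedure was tested on simulated data. For 17beta-estradiol at 48 h with 4593 genes, 11 of 50 genes changed 1.25-fold were recovered, 35 of 50 at 1.5-fold, 48 of 50 at 2-fold and 50 of 50 at 3-fold, with 2 false calls among 4276 unchanged genes. For the concentration trend of 17beta-estradiol, 99 of 100 simulated slopes of 0.5 (log2 per log10 concentration) were recovered. Smaller slopes were not simulated.

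Alternatives were Agilent's log ratios, median centring, no or a stricter filter on dim probes (50%), the 4 controls of a time as 1 group, the controls of the other sets, separate channels (Aquantile), a dye term per time campaign or none, the spread of 1 time alone, a trended and robust prior, the mean of all probes, the series matrix, repeated extract names as 2 extracts, and leaving out each concentration. Chosen after seeing the data were: leaving out the array with the most outlier spots (33.9%, the next 6.57%), leaving out the worst closing loop, a dye term per scan day, slide as a random block (duplicateCorrelation, correlation 0.21) and leaving out each time from the pairs of compounds. The 101 slides held 1 or 2 arrays and the 19 scan days separated the 48 h arrays (8 days) from the others (11 days), so time point, scanning campaign and software version cannot be told apart. Every compound was compared with a control of its own time. The tools were R 4.3.3, limma 3.58.1, the data.table package (1.17.8), statmod 1.5.0, Python 3.11.15 and matplotlib 3.10.9.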

Results

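The series screened 20 compounds for estrogenic activity by their effect on gene expression in MCF-7 breast cancer cells, with 17beta-estradiol, the natural ligand of the estrogen receptor, as the reference. Of the compounds, 19 were pesticides, industrial chemicals, dioxin-like ligands, a phytoestrogen or other hormones. RNA was taken after 1, 4 and 48 h, mostly at 2 concentrations (3 for 17beta-estradiol and endosulfan), and compared with 1 solvent control extract per set and time. 17beta-estradiol was used at 1, 10 and 100 nM and endosulfan at 5, 10 and 20 uM. TCDD (1 and 10 nM), bisphenol A and testosterone (10 and 100 nM) and thyroid hormone (15 and 150 nM) were in the nanomolar range. Of the others, p,p'-DDT, toxaphene, kepone and dimethyl-benz(a)anthracene were used at 1 and 5 uM, nonylphenol, benzo(a)pyrene and genistein at 1 and 10 uM, and PCB126 at 2 and 10 uM. Methoxychlor was used at 5 and 15 uM, diethylhexylphthalate and tetrabromobisphenol A at 5 and 10 uM, dicyclohexylphthalate at 10 and 25 uM, atrazine at 10 and 40 uM and lindane at 25 and 50 uM. Thyroid hormone at 1 and 4 h (15 nM), genistein at 1 h (1 uM), and p,p'-DDT (5 uM) and PCB126 (10 uM) at 4 h had a single extract, which was assumed to vary like the others. For one of the 2 nonylphenol extracts at 4 h the source name gives 10 and the concentration label 1 uM, and its concentration was left open. The source names of bisphenol A give other numbers than its labels, and the same one for both extracts at 48 h. Its concentrations therefore rest on the labels alone. The source names of p,p'-DDT 5 uM at 1 and 4 h read dtt, and the compound label was followed. The 183 arrays measured 4593 genes in 121 treated and 12 control extracts, and a median of 90.2% of spots were well above background. Changes are log2 differences from the matched solvent control ± 1 standard error, with n the number of extracts at different concentrations. Each of the 4 controls at 48 h, set against the other 3, differed in 1 to 25 genes.

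After 1 h, 17beta-estradiol had raised 3 genes and lowered none (0; 25 genes at an unadjusted p under 0.05, limma). The immediate early gene FOS, a subunit of the AP-1 transcription factor, rose by 1.96 ± 0.29 (n = 3, adjusted p = 8.8e-06). The stress-inducible genes GADD45G and GADD45B rose by 1.14 ± 0.15 (adjusted p = 3.4e-07) and 0.84 ± 0.16 (adjusted p = 0.0047). The immediate early list as a whole was higher by 0.24 (adjusted p = 4.8e-09, and adjusted p = 0.0042 with an estimated correlation), although 1 of its 18 genes passed over all genes and 2 adjusted over the list alone. The estrogen-induced list was 0.10 higher (adjusted p = 0.025, but adjusted p = 0.64 with an estimated correlation), with 0 of 17 genes passing. The aryl hydrocarbon receptor list was -0.22 and the endoplasmic reticulum stress list -0.08 relative to control (adjusted p = 9.0e-04 and 0.0071; adjusted p = 0.088 and 0.076 with an estimated correlation), and no member of either passed (0 genes). The 1 h controls, each against the others, ranged from -0.59 (the control used here) to 0.56 on the aryl hydrocarbon receptor list. The fall of -0.22 was smaller than that spread. The control used was the lowest, so the other controls would give a larger fall. The number of genes changed at 1 h was 35 with the 4 controls as 1 group, 67 with the other sets' controls and 8 when repeated extract names were taken as separate extracts.

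After 4 h, the response comprised 254 genes, 176 higher and 78 lower, of which 29 and 10 changed more than 2-fold. The largest rises included the transcription factors MYB (2.04 ± 0.55), EGR3 (1.97 ± 0.32), FOS (1.75 ± 0.29) and FOXC1 (1.68 ± 0.25), the retinoic acid hydroxylase CYP26B1 (1.96 ± 0.37) and the mitochondrial cyclophilin PPIF (1.65 ± 0.27). The receptors NPY1R (1.59 ± 0.39) and CALCR (1.53 ± 0.37), the EGF receptor ligand AREG (1.59 ± 0.49) and a probe that the files name only as M31213 (2.14 ± 0.33) completed the 10 (n = 3, adjusted p between 2.2e-06 and 0.041). The largest falls were in the kinase CDK6 (-1.41 ± 0.22, although its second probe gave -0.04), the xenobiotic-metabolising enzyme CYP1A1 (-1.38 ± 0.37, but -0.86 against the mean of the other 3 controls), the prostaglandin receptor PTGER4 (-1.35 ± 0.26) and the glucocorticoid receptor NR3C1 (-1.29 ± 0.19). TGFB3 (-1.12 ± 0.21), PLK2 (-1.07 ± 0.19), ID1 (-1.07 ± 0.21), TP63 (-1.06 ± 0.32), LMO7 (-1.05 ± 0.30, second probe -0.54) and CCNG2 (-1.01 ± 0.24) followed (adjusted p between 6.3e-07 and 0.035).

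Estrogen-induced genes rose together at 4 h, by 0.99 on average (interval 0.56 to 1.42). Of the 17 genes, 11 rose over all genes tested and 15 adjusted over the list alone. Among them were PGR (1.51), CXCL12 (1.49), MYC (1.476), RAPGEFL1 (1.17) and CCND1 (0.74). The list differed from other genes (adjusted p = 7.0e-18, and adjusted p = 0.015 with an estimated correlation). Estrogen-repressed genes averaged -0.45. CCNG2, TGFB3 and EFNA1 (-0.78) fell while PDCD4, an inhibitor of translation, rose by 0.43. Of the 8 genes 6 passed adjusted over the list alone (adjusted p = 9.5e-05; adjusted p = 0.024 with an estimated correlation). In the immediate early list 8 of 18 genes rose and IER3 fell by 0.66, and 10 genes passed adjusted over the list alone. That list averaged 0.46 (adjusted p = 2.0e-04; adjusted p = 0.080 with an estimated correlation). The NRF2 target list averaged -0.19, with HMOX1 (-0.91), a haem-degrading enzyme, and ME1 (-0.29) falling (adjusted p = 0.024; adjusted p = 0.18 with an estimated correlation). The aryl hydrocarbon receptor list averaged -0.58 with CYP1A1 alone passing over all genes (adjusted p = 0.0026; adjusted p = 0.13 with an estimated correlation). The 27 cell cycle genes averaged 0.03 and none passed (0 genes; adjusted p = 0.84). The 4 h count was 593 with the 4 controls as 1 group, 630 with the other sets' controls and 461 with repeated names as separate extracts. Median centring gave 107 genes higher and 81 lower.

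After 48 h, 17beta-estradiol had changed 1240 of 4592 genes, 623 higher and 617 lower, with 94 and 91 changing more than 2-fold. The largest rises were in AREG (3.76 ± 0.49), NPY1R (3.36 ± 0.39), CYP26B1 (2.52 ± 0.37), the progesterone receptor PGR (2.51 ± 0.39) and MYB (2.49 ± 0.55). The lysosomal galactosidase GLA (2.31 ± 0.27), the ribonucleotide reductase subunit RRM2 (2.09 ± 0.33), the mitotic kinase PBK (2.07 ± 0.29) and the chemokines CXCL12 (2.08 ± 0.29) and CXCL14 (2.01 ± 0.41) followed (n = 3, adjusted p at most 2.3e-04). The largest falls were in the surface antigen PSCA (-4.01 ± 0.51), the hypoxia-inducible factor EPAS1 (-3.90 ± 0.53, although its second probe gave -0.29), the retinaldehyde dehydrogenase ALDH1A3 (-3.04 ± 0.46) and the stress cytokine GDF15 (-2.98 ± 0.36). ACAA2 (-2.73 ± 0.36), LMCD1 (-2.61 ± 0.26), TP63 (-2.53 ± 0.32), the copper transporter SLC31A2 (-2.37 ± 0.37), NCF2 (-2.32 ± 0.29) and the Notch target HES1 (-2.30 ± 0.29) completed them (adjusted p at most 4.9e-07).

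Genes of cell division rose as a group at 48 h. Of the 27 cell cycle genes 26 rose over all genes and 27 adjusted over the list alone, by 1.19 on average (0.82 to 1.57). RRM2, TYMS (1.79), CCNB2 (1.76), BIRC5 (1.70) and CDK1 (1.65) rose most, and CDC25A (0.17) did not pass over all genes. The list differed from other genes (adjusted p = 7.8e-22; adjusted p = 0.061 with an estimated correlation). The estrogen-induced list was higher by 1.20 (0.77 to 1.63), with 14 of 17 genes up by either adjustment, over all genes or adjusted over the list alone (adjusted p = 1.7e-08; adjusted p = 0.061 with an estimated correlation). IGFBP4 (0.26), MYC (0.03) and CCND1 (-0.33) did not pass. Of the sterol synthesis genes, 10 of 11 rose, including HMGCS1 (0.89), IDI1 (0.81), DHCR7 (0.74) and HMGCR (0.59), while SC5D fell by 0.42. The list averaged 0.50 and 11 genes passed adjusted over the list alone (adjusted p = 1.1e-06; adjusted p = 0.019 with an estimated correlation).

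Lists that were lower at 48 h included the p53 targets, in which 6 of 15 genes fell, among them GDF15, CDKN1A (-1.49), GADD45A (-1.43) and BTG2 (-1.35). The list averaged -0.59 with a median of -0.11 (adjusted p = 0.0011; 6 genes adjusted over the list alone). In the estrogen-repressed list ERBB2 (-1.35), CCNG2 (-1.30), EFNA1 (-1.09), BIK (-0.87) and TGFB3 (-0.69) fell and PDCD4 rose by 0.62. The list averaged -0.63 (adjusted p = 0.0021; 7 of 8 adjusted over the list alone). Of the immediate early genes 10 fell, with EGR1 (-2.00), IER3 (-1.44), JUN (-1.36) and DUSP1 (-1.20) foremost, and FOS (0.89), EGR3 (1.37), SGK1 (0.65) and NR4A2 (0.41) rose. The list averaged -0.43 (adjusted p = 0.0016; 15 adjusted over the list alone). In the aryl hydrocarbon receptor list ALDH1A3, the quinone reductase NQO1 (-1.30), the glucuronosyltransferase UGT1A6 (-1.08) and CYP1A2 (-0.28) fell. CYP1A1 (-0.37, adjusted p = 0.60) and CYP1B1 (-0.54, adjusted p = 0.089) did not pass. The list averaged -1.10 (adjusted p = 3.9e-04; 5 of 6 adjusted over the list alone). None of these 4 calls held with an estimated correlation (adjusted p = 0.061 with an estimated correlation for 3 of them and 0.092 for the immediate early list). The NRF2 (-0.35, adjusted p = 0.10), endoplasmic reticulum stress (-0.23, adjusted p = 0.13) and thyroid hormone (-0.22, adjusted p = 0.24) lists did not pass. The stromal and immune markers, COL1A1, COL1A2, COL3A1, PTPRC and PECAM1, averaged 0.03 with 0 of 5 passing (adjusted p = 0.64), and with no compound or time did that list pass (0 of 20 compounds at each time). Of these markers PTPRC and PECAM1 were dim (mean log2 brightness 6.297 and 6.314 in the set 10 control of 1 h), so a fall of them could hardly be seen. With slide as a random block the estrogen-induced list gave 1.20 and with a dye term per scan day 1.22. Within the loops that held both a 17beta-estradiol extract and its control the 3 concentrations gave 1.24, 1.22 and 1.15.

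**Figure D1:**
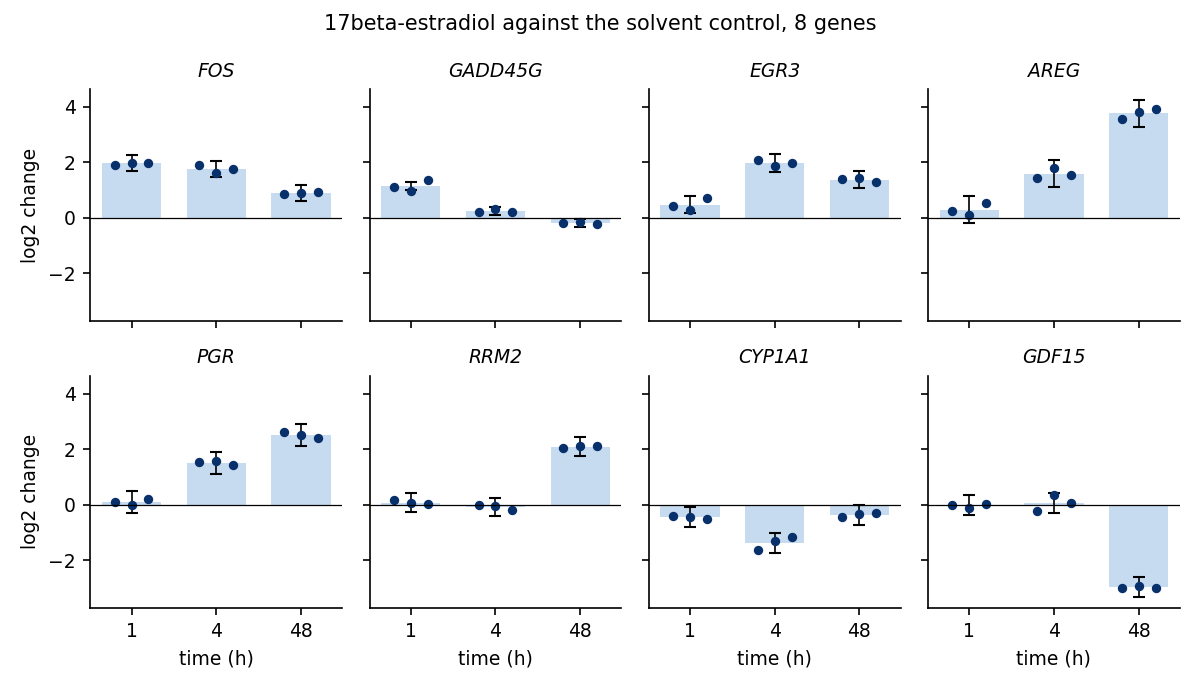
Log2 change of 8 genes (y axis) after 1, 4 and 48 h of 17beta-estradiol (x axis), with bars for the mean over 3 concentrations, points for 1, 10 and 100 nM and error bars of 1 standard error from the fit. FOS was highest at 1 h (1.96), whereas AREG, PGR and RRM2 were highest at 48 h (3.76, 2.51 and 2.09) and GDF15 was lowest then (-2.98).

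The 17beta-estradiol effect differed between 48 and 4 h in 653 genes, 304 with a more positive and 349 with a more negative change at 48 h. Of these, 21 rose at 4 h and fell at 48 h, and 3 did the opposite. Cell cycle genes differed most, by 1.16 (0.63 to 1.68; adjusted p = 6.9e-21, and adjusted p = 0.055 with an estimated correlation). Sterol synthesis genes were higher at 48 h by 0.48 (adjusted p = 1.5e-06; adjusted p = 0.011 with an estimated correlation). Immediate early genes were lower at 48 h than at 4 h by -0.89 (adjusted p = 4.8e-08; adjusted p = 0.011 with an estimated correlation) and p53 targets by -0.54 (adjusted p = 0.0073; adjusted p = 0.18 with an estimated correlation). The estrogen-induced list differed by 0.21 (-0.40 to 0.82; adjusted p = 0.49). Both times shared 56 risen genes (23.9 for independent lists) and 49 fallen genes (10.5 for independent lists). The 653 became 1186 with the 4 controls as 1 group, 1088 with the other sets' controls, 1041 with repeated names as separate extracts and 406 with median centring. No gene followed the concentration of 17beta-estradiol from 1 to 100 nM (0 genes with limma, lowest adjusted p = 1.00; 118 at an unadjusted p under 0.05 where chance gives 229.6), and leaving out 100 nM at 1 h gave 1 gene.

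At 48 h several other compounds moved the genes that 17beta-estradiol moved most. AREG rose with genistein, a soy isoflavone (3.99 ± 0.53), testosterone (3.20 ± 0.53), nonylphenol, a surfactant breakdown product (3.08 ± 0.53), the insecticide kepone (2.97 ± 0.53), dicyclohexylphthalate (2.59 ± 0.53) and lindane (1.81 ± 0.53). NPY1R was among the 2 largest rises with genistein (3.29), dicyclohexylphthalate (2.75), nonylphenol (2.65), kepone (2.45) and thyroid hormone (1.73). MYB was among them with testosterone (2.57), methoxychlor (2.42) and lindane (1.92). The largest fall was in PSCA with genistein (-3.86), nonylphenol (-3.35) and lindane (-2.02). It was in EPAS1 with kepone (-3.38), dicyclohexylphthalate (-3.22), methoxychlor (-2.42), testosterone (-2.34) and thyroid hormone (-1.89). With thyroid hormone EPAS1 was at -0.49 and -3.29 and NPY1R at 0.77 and 2.68 at 15 and 150 nM, so both rest mainly on the higher concentration, for which a wrong label is not excluded. The second EPAS1 probe gave -0.14 to -0.40 in these. The carbonic anhydrase CA2 rose with methoxychlor (2.22), the GDNF receptor GFRA1 with thyroid hormone (1.88) and with endosulfan (1.56), and PCLAF with endosulfan (1.41, second probe 0.04), where TP63 fell by 1.23. Each had n = 2 (n = 3 for endosulfan) and an adjusted p of at most 0.031.

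Genistein changed more genes at 48 h than any other compound, 764 higher and 647 lower. Nonylphenol changed 592 and 546, kepone 503 and 531, testosterone 526 and 345, dicyclohexylphthalate 384 and 412, lindane 294 and 248, methoxychlor 279 and 191, thyroid hormone 161 and 139, and endosulfan 70 and 40. With tetrabromobisphenol A 31 genes were higher and 6 lower, led by BCO2 (1.41), BIRC2 (0.58) and POLM (-0.49). The last pair rested on the set 12 control: against the mean of the other 3 controls BIRC2 was at 0.12 and POLM at -0.19 (BCO2 0.98), and the mean log2 brightness of BIRC2 was 8.979 treated and 8.990 in the control. Toxaphene lowered OXTR (-0.86) and, outside the rule for named genes and chosen after its value was seen, S100A6 (-0.71). Diethylhexylphthalate raised BCO2 alone (2.20, adjusted p = 6.4e-04, n = 1 since 5 uM had no value), likewise named after its value was seen. No gene passed with p,p'-DDT, bisphenol A or atrazine (0 genes with limma; 504, 200 and 370 at an unadjusted p under 0.05). Over the 19 compounds the calls summed to 8240, and to 17495 with the 4 controls as 1 group, 18188 with the other sets' controls, 14184 with repeated names as separate extracts and 3257 with the spread of 48 h alone.

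The estrogen-induced list, set against all other genes and adjusted over the 20 compounds, was higher at 48 h with 14 compounds. Genistein (1.28, interval 0.82 to 1.74) and nonylphenol (1.27, 0.81 to 1.72) lay beside 17beta-estradiol (1.20). Testosterone (1.03, 0.58 to 1.49), kepone (1.02, 0.57 to 1.5), dicyclohexylphthalate (0.97, 0.51 to 1.43), methoxychlor (0.89, 0.44 to 1.35), lindane (0.82, 0.36 to 1.28) and thyroid hormone (0.73, 0.27 to 1.19) followed. Of its 17 genes, 14 rose with genistein and with nonylphenol, 12 with testosterone and dicyclohexylphthalate, 11 with kepone, methoxychlor and lindane and 6 with thyroid hormone. Adjusted over the list alone the counts were 15, 15, 14, 13, 13, 14, 13 and 11. PGR rose with each of them, from 1.30 with thyroid hormone to 2.42 with nonylphenol. The list was also higher with p,p'-DDT (0.52, 0.06 to 0.98), endosulfan (0.44, 0.01 to 0.88), toxaphene (0.44), diethylhexylphthalate (0.37) and bisphenol A (0.24), where 0 genes passed over all genes and at most 2 adjusted over the list alone. It did not pass with TCDD (0.25, adjusted p = 0.13), benzo(a)pyrene (0.21, adjusted p = 0.40), dimethyl-benz(a)anthracene (0.16, adjusted p = 0.18), tetrabromobisphenol A (0.07), PCB126 (0.01, with a median of -0.11 and a test pointing down) or atrazine (-0.04). The 4 controls, each against the others, lay between -0.05 and 0.05. No call held with an estimated correlation (0 compounds; adjusted p = 0.087 with an estimated correlation for 10 compounds). The value was 0.20 for endosulfan, 0.22 for toxaphene, 0.23 for diethylhexylphthalate and 0.32 for bisphenol A. The interval of the mean excluded 0 for 11 compounds.

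**Figure D2:**
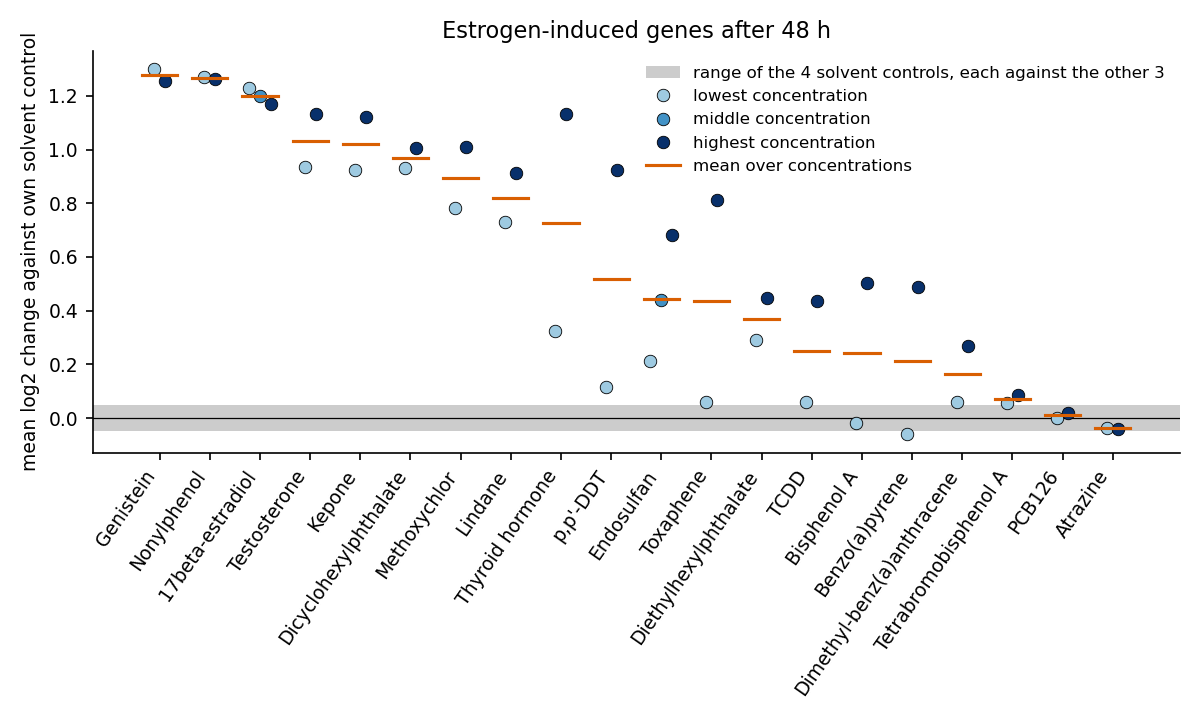
Mean log2 change of the 17 estrogen-induced genes against the own solvent control (y axis) in each extract of the 20 compounds (x axis) at 48 h, with points for each concentration, lines for the compound mean and a grey band for the range of the 4 controls (-0.05 to 0.05). Genistein, nonylphenol and 17beta-estradiol lie highest (1.28, 1.27 and 1.20), and the concentrations of thyroid hormone, p,p'-DDT and toxaphene lie far apart.

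Concentrations of a compound differed most for thyroid hormone, p,p'-DDT and toxaphene. The estrogen-induced list was 0.32 at 15 nM and 1.133 at 150 nM thyroid hormone, 0.11 at 1 and 0.92 at 5 uM p,p'-DDT, and 0.06 at 1 and 0.81 at 5 uM toxaphene. Set against the control as single extracts these changed 13 and 698, 0 and 399, and 0 and 520 genes. Without the higher concentration the list no longer passed with toxaphene (0.06) or bisphenol A (-0.02 at 10 nM, against 0.50 at 100 nM). Without the lower one it did pass with benzo(a)pyrene (0.49 at 10 uM, -0.06 at 1 uM) and TCDD (0.44 at 10 nM, 0.06 at 1 nM). Endosulfan gave 0.21, 0.44 and 0.68 at 5, 10 and 20 uM. At the lowest and highest concentrations 17beta-estradiol gave 1.23 and 1.17, genistein 1.30 and 1.26, and nonylphenol 1.27 and 1.26.

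Over the 1240 genes that 17beta-estradiol changed at 48 h (1239 for compounds of set 13), the slope of the other compound's change on that of 17beta-estradiol was 0.92 for genistein (r = 0.96), 0.83 for kepone (r = 0.97), 0.81 for nonylphenol, 0.75 for dicyclohexylphthalate (r = 0.97) and 0.73 for testosterone. These correlations run across genes, which are not independent replicates. Slopes were 0.57 for lindane, 0.56 for methoxychlor, 0.51 for thyroid hormone, 0.41 for p,p'-DDT and 0.33 for diethylhexylphthalate, and between -0.06 and 0.10 for the controls of the other sets. Genes risen with both 17beta-estradiol and genistein numbered 495 (103.7 for independent lists) and fallen with both 419 (86.9). For kepone they were 436 (68.3) and 439 (71.4), and for testosterone 412 (71.4) and 290 (46.4). Calls in opposite directions were found for benzo(a)pyrene (80), PCB126 (59), TCDD (6), tetrabromobisphenol A (2) and testosterone (2) and for no other compound (0). Endosulfan (slope 0.43) shared its control with 17beta-estradiol: its correlation over all genes was 0.87 against 0.75 in 100 simulations of unchanged groups, and its covariance 0.075 against 0.010.

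The cell cycle list was higher at 48 h with 19 of the 20 compounds, by means of up to 1.19, the exception being atrazine (0.08, adjusted p = 0.34). No member passed over all genes (0 of 27) with p,p'-DDT, toxaphene, diethylhexylphthalate, bisphenol A, tetrabromobisphenol A or dimethyl-benz(a)anthracene; adjusted over the list alone 23, 25, 20, 0, 0 and 0 did. Bisphenol A gave 0.03 at 10 nM and 0.62 at 100 nM. The interval excluded 0 for 16 compounds and 11 of the 19 calls held with an estimated correlation. The 4 controls, each against the others, ranged from -0.19 to 0.20. Across the 20 compounds and within sets, the mean of the cell cycle list went with that of the estrogen-induced list (Pearson's r = 0.953, Spearman's rho = 0.929, permutation p = 1e-05 for each, the smallest possible here; r = 0.930 without genistein and nonylphenol). At 1 and 4 h the list passed with no compound (0 of 20, limma's cameraPR).

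**Figure D3:**
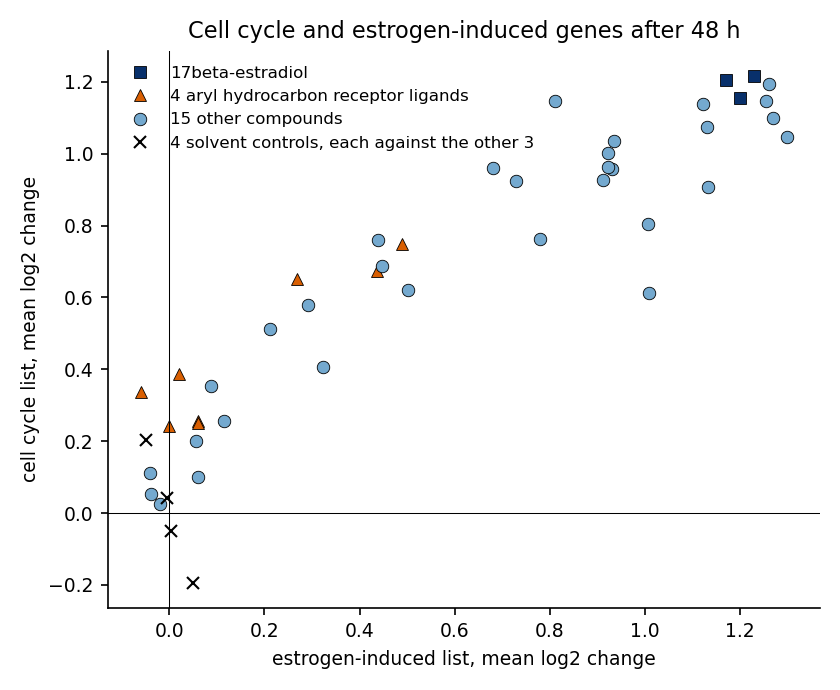
Mean log2 change of the estrogen-induced list (x axis) and of the cell cycle list (y axis) in each treated extract at 48 h, with squares for 17beta-estradiol, triangles for the 4 aryl hydrocarbon receptor ligands, circles for the 15 other compounds and crosses for the 4 controls, each against the other 3. Extracts with a higher estrogen-induced list mostly had a higher cell cycle list, the latter reaching 1.22 with 17beta-estradiol, while the controls reached 0.20.

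At 4 h the estrogen-induced list was already higher with 16 compounds. The largest means after 17beta-estradiol were those of genistein (0.95), nonylphenol (0.93), methoxychlor (0.82), dicyclohexylphthalate (0.79), p,p'-DDT (0.72), kepone (0.72) and benzo(a)pyrene (0.65). Then came lindane (0.54), toxaphene (0.50), testosterone (0.49), diethylhexylphthalate (0.40), thyroid hormone (0.30), dimethyl-benz(a)anthracene (0.29), endosulfan (0.26) and bisphenol A (0.25). The single thyroid hormone extract gave 0.13 within one of its loops and 0.51 within the other. Dimethyl-benz(a)anthracene was at 0.12 and 0.45 and bisphenol A at 0.08 and 0.42 at the lower and higher concentration. It did not pass with PCB126 (-0.06), atrazine (0.04), tetrabromobisphenol A (0.12) or TCDD (0.14). The call held with an estimated correlation for 10 compounds, and the interval excluded 0 for 11. Genes changed numbered 195 with genistein, 156 with nonylphenol, 109 with methoxychlor, 79 with kepone, 51 with dicyclohexylphthalate, 44 with lindane, 37 with benzo(a)pyrene, 16 with dimethyl-benz(a)anthracene, 10 with p,p'-DDT, 8 with PCB126 and 7 with testosterone. Named after their values were seen, KAT6B (0.71) and MAP4K1 (0.50) rose with atrazine, CMTM3 (0.69) rose with TCDD and DNAJA1 fell by 0.52 with endosulfan. No gene passed with toxaphene, diethylhexylphthalate, tetrabromobisphenol A, bisphenol A or thyroid hormone (0 genes with limma; 136, 229, 112, 17 and 215 at an unadjusted p under 0.05).

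At 1 h the immediate early list passed with 14 of 20 compounds, higher in 11 and lower in 3, and 4 of these calls held with an estimated correlation. Over all genes 4 of its 18 members passed with nonylphenol, 2 with genistein, 1 each with 17beta-estradiol and bisphenol A, and 0 with the other 10. The 1 h controls, each against the others, ranged from -0.26 to 0.17 on this list, as wide as many of the means (atrazine 0.13, tetrabromobisphenol A -0.14, genistein 0.24). FOS and GADD45G rose with nonylphenol (1.88 and 1.44) and genistein (1.47 and 1.32), and MYC (1.86) and GADD45B (1.22) rose with genistein. The inhibitors of DNA binding ID1 (-0.96), ID2 (-1.02) and ID3 (-0.76) and the orphan receptor NR4A1 (-0.92) fell with bisphenol A. CYP1A1 was at -1.57 with nonylphenol and -1.83 with toxaphene, but the set 11 control of both stood 1.92 above the mean of the other 3 controls, against which the values were 0.35 and 0.09. Genes of the 1 h comparisons outside the fixed lists were named after their values were seen. The estrogen-induced list passed with nonylphenol (0.29), genistein (0.25, adjusted p = 0.0044), kepone (0.16) and 17beta-estradiol (0.10). None of the 4 calls held with an estimated correlation (adjusted p = 0.99 with an estimated correlation for 17beta-estradiol), and 0 intervals excluded 0. Without genistein 1 uM, its only extract at 1 h, no compound passed (0), and without kepone 5 uM or without nonylphenol 1 uM 1 compound did. Genes changed numbered 45 with TCDD (3 higher, 42 lower), 37 with nonylphenol, 13 with bisphenol A, 13 with genistein and 9 with methoxychlor. The set 13 control of 1 h, which TCDD was set against, was higher than the other 3 controls in 23 genes and lower in 8, the most of the 4. Whether the TCDD calls rest on that control was not tested. Toxaphene also lowered DLL1 (-0.72) and raised ID1 (0.98), and p,p'-DDT raised CDY2A (0.55) and lowered DLL1 (-0.71). Both compounds were set against the set 11 control, which was higher than the other 3 in 7 genes. Whether the DLL1 falls rest on that control was not tested. Diethylhexylphthalate lowered QPRT (-1.26) and FLJ11021 (-0.40), kepone raised SOCS1 (0.74) and thyroid hormone lowered ZNF345 (-0.43). No gene passed with the remaining 9 compounds (0 genes with limma; 5 to 407 at an unadjusted p under 0.05).

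TCDD, PCB126, benzo(a)pyrene and dimethyl-benz(a)anthracene are ligands of the aryl hydrocarbon receptor, a sensor of planar aromatic compounds. Taken as 1 group at 48 h (n = 8 extracts, 3 controls), they changed 779 genes, 394 higher and 385 lower. The monooxygenases CYP1A1 (2.88 ± 0.23) and CYP1B1 (2.36 ± 0.15) rose most, from 1.07 and 0.85 with dimethyl-benz(a)anthracene to 3.74 and 3.90 with PCB126. AREG (0.97 ± 0.30), the efflux transporter ABCG2 (0.89 ± 0.13), the DNA damage sensor DDB2 (0.84 ± 0.09), TYMS (0.83 ± 0.17), STC2 (0.81 ± 0.16) and CDCA2 (0.80 ± 0.15, second probe 0.29) followed. Over the 4 ligands DDB2 ran from 0.29 to 2.09, the latter with benzo(a)pyrene. TYMS ran from 0.35 to 1.75, STC2 from 0.24 to 1.31 and AREG from 0.59 to 1.83. ABCG2 (0.57 to 1.15) and CDCA2 (0.70 to 0.955) varied less. The Wnt inhibitor DKK1 (-1.32 ± 0.10), BMP7 (-1.27 ± 0.12), fibronectin FN1 (-1.26 ± 0.15, second probe -1.22), KLK6 (-1.24 ± 0.18, second probe -0.23) and EGR1 (-1.22 ± 0.20) fell most (adjusted p at most 0.017 for each gene). The count was 348 with the spread of 48 h alone, and median centring gave 357 higher and 218 lower.

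By compound, the 6-gene aryl hydrocarbon receptor list rose with PCB126 (1.58, 1.15 to 2.00), TCDD (1.27, 0.85 to 1.70) and benzo(a)pyrene (1.117, 0.69 to 1.54), with 3, 2 and 3 genes up over all genes. Adjusted over these 4 ligands, the calls of PCB126 and TCDD (adjusted p = 1.5e-06 each) held at adjusted p = 0.0061 with an estimated correlation. That of benzo(a)pyrene (adjusted p = 0.0029) was lost at adjusted p = 0.089 with an estimated correlation. PCB126 was set against the set 12 control, the lowest on this list (-0.25 against the other 3). TCDD was set against that of set 13, the highest (0.10), so the order of PCB126 and TCDD is not settled. With dimethyl-benz(a)anthracene the mean was 0.31 (-0.11 to 0.73; adjusted p = 0.017, lost at adjusted p = 0.15 with an estimated correlation, and 0.08 without 5 uM). Over all genes 0 members passed, and 2 adjusted over the list alone; CYP1A1 was at 1.07 (adjusted p = 0.52). PCB126 changed 353 genes up and 292 down, benzo(a)pyrene 321 and 365, TCDD 68 and 124, and dimethyl-benz(a)anthracene 2 and 3. FDXR (2.17) rose and MSRA fell by 1.91 (second probe -0.18) with benzo(a)pyrene, DKK1 fell by 2.28 with PCB126 and KLK6 by 1.61 with TCDD (second probe -0.32). The 5 genes of dimethyl-benz(a)anthracene were FDXR (0.64), PSMA7 (0.38) and IGFBP7 (-0.83), and FYN (-0.37) and HSD17B6 (-0.39), the last pair outside the rule and named after their values were seen. PCB126 had raised CYP1A1 (1.91) and CYP1B1 (1.56) by 4 h.

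**Figure D4:**
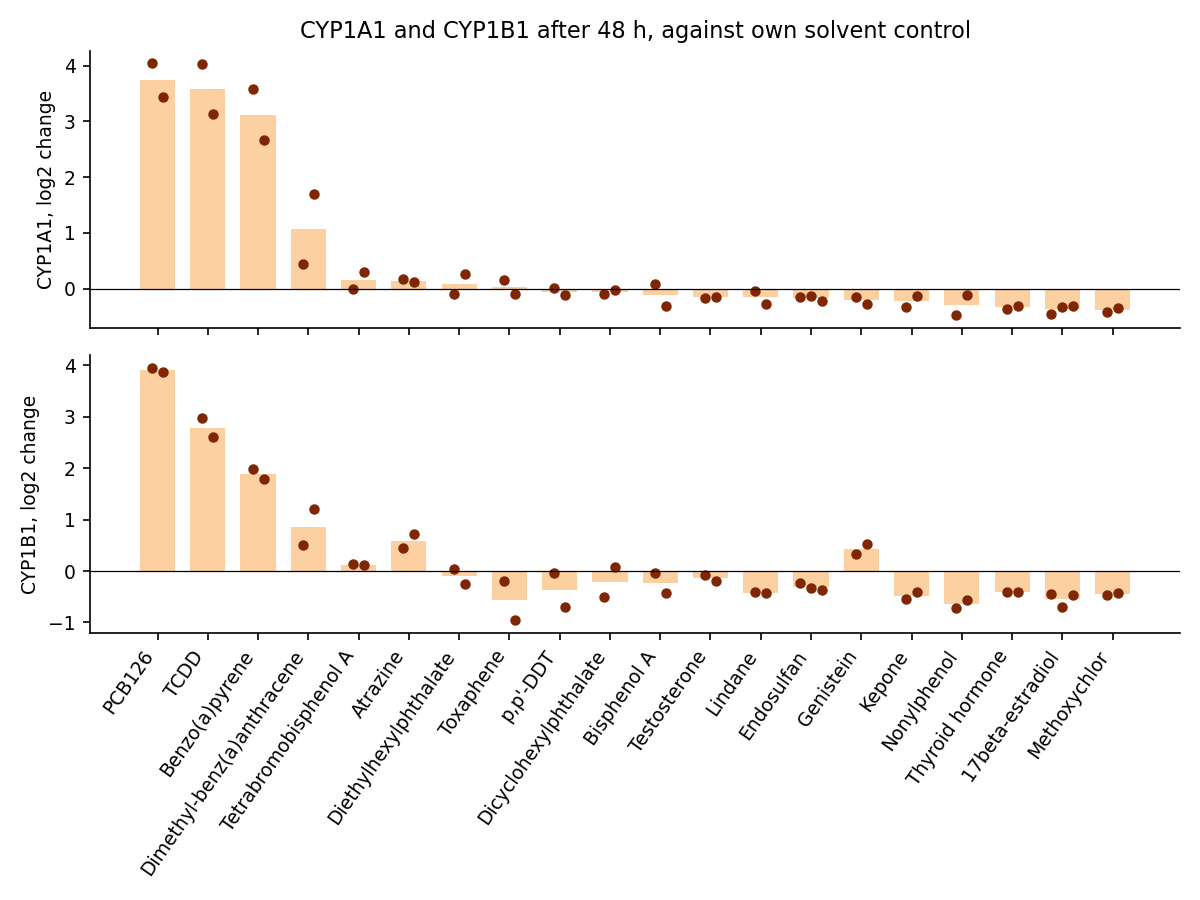
Log2 change of CYP1A1 (y axis, top) and CYP1B1 (y axis, bottom) at 48 h with each of the 20 compounds (x axis), with bars for the mean and points for each concentration. PCB126 and TCDD stand highest (3.74 and 3.58 for CYP1A1, 3.90 and 2.79 for CYP1B1). In CYP1B1 their mean log2 brightness was 15.7 and 15.51, and 11.55 and 12.56 in their controls. The values of 17beta-estradiol lie below 0 in both panels (-0.37 and -0.54).

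In 13 compounds the aryl hydrocarbon receptor list was lower at 48 h, and it was higher in the 4 ligands alone; 2 of these 17 calls held with an estimated correlation. ALDH1A3 and UGT1A6 fell in 8 of the 13, and NQO1 in all of these but lindane, for instance with changes of -2.86, -0.97 and -1.45 with kepone and -2.58, -0.85 and -1.51 with genistein. No fall of CYP1A1 passed, and no member passed with endosulfan, p,p'-DDT, toxaphene, diethylhexylphthalate or thyroid hormone. Adjusted over compounds, the immediate early list was lower with 15 compounds, the estrogen-repressed list lower with 9 and the sterol synthesis list higher with 8; of these calls 0, 0 and 1 held with an estimated correlation.

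Testosterone and thyroid hormone were each set against a list of their own receptor's targets. Of the androgen-induced list the array tested NDRG1 alone, which fell with testosterone by 0.75 ± 0.25 (n = 2, adjusted p = 0.022) and with 17beta-estradiol by 1.09 ± 0.23 (n = 3, adjusted p = 1.5e-04). The thyroid hormone-induced list, DIO1 (-0.08), BCL3 (-0.35) and ME1 (0.02), averaged -0.13 with thyroid hormone (-0.26 to -0.004; adjusted p = 0.32; adjusted p = 0.41 with an estimated correlation) and 0 of the 3 genes passed.

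Structurally related compounds were compared on the estrogen-induced list at shared concentrations, averaged over the 3 times. Methoxychlor carries methoxy groups where p,p'-DDT carries chlorines on its rings. At 5 uM the list averaged 0.57 with each (difference -0.005, -0.31 to 0.30; adjusted p = 0.57), with 0.92 for p,p'-DDT and 0.78 for methoxychlor at 48 h. Over all genes these 2 differed in 1079 genes at 1 h, 5 at 4 h and 2 at 48 h. 17beta-estradiol has an aromatic A ring where testosterone has an enone. At 10 and 100 nM the list averaged 0.76 and 0.51 (difference 0.25, -0.12 to 0.62; adjusted p = 1.4e-04; adjusted p = 0.30 with an estimated correlation). At 4 h they were 0.98 and 0.49, and 4 genes differed over all times, 1 at 1 h, 15 at 4 h and 21 at 48 h. The list was higher with 17beta-estradiol in 6 of 6 pairs of extracts matched by concentration and time. Without 4 h the difference was 0.13. Diethylhexylphthalate has branched alkyl esters where dicyclohexylphthalate has cyclohexyl esters. At 10 uM they averaged 0.31 and 0.56 (difference -0.26, -0.69 to 0.17; adjusted p = 3.1e-05; adjusted p = 0.30 with an estimated correlation). It was below 0 in 3 of 3 matched pairs and -0.15 without 48 h. The polycyclic hydrocarbons benzo(a)pyrene and dimethyl-benz(a)anthracene at 1 uM averaged 0.20 and 0.05 (difference 0.15, -0.28 to 0.58; adjusted p = 0.10). At 4 h they were 0.62 and 0.12 (adjusted p = 1.8e-07; adjusted p = 0.15 with an estimated correlation). Without 4 h the sign turned (-0.03), and 14 genes differed over all times and 338 at 48 h. Tetrabromobisphenol A is bisphenol A with bromines on its rings, but the concentrations differed. At 48 h the list was -0.02 and 0.50 at 10 and 100 nM bisphenol A and 0.06 and 0.09 at 5 and 10 uM tetrabromobisphenol A.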

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

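The 3 tests of the cell cycle pattern were chosen only after the result was seen.

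The aryl hydrocarbon receptor list at 48 h set the control of set 12 apart from the other 3 controls (-0.18 against 0.06, 0.05 and 0.07), with a gap of 0.91 of the whole range. Of 33 groups of 4 controls tested in this way 1 stood out, where chance gives about 1 in 20. PCB126, whose rise on this list is given above, was set against this control.

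The 17beta-estradiol effect differed between 48 and 4 h in 653 genes, and in 4 of the lists: the cell cycle genes by 1.16, the immediate early genes by -0.89, the p53 targets by -0.54 and the sterol synthesis genes by 0.48, each by a test of the difference itself. With an estimated correlation the calls of the cell cycle genes (adjusted p = 0.055) and p53 targets (adjusted p = 0.18) were lost and the other 2 held (adjusted p = 0.011 each). Arrays of the 2 times were scanned in separate campaigns with separate software versions, and each effect was taken against a control of its own time.

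Cell cycle genes were higher than in the solvent control in 42 of 42 treated extracts at 48 h. Controls that had divided less than any treated culture would lift all extracts of a set, and the lowest extract lay above the highest control value (0.20) in 2 of the 4 sets. It was at 0.51 in set 10, 0.25 in set 13, 0.03 in set 11 and 0.05 in set 12, which argues against slow controls as the whole cause. Sets 10 and 13 held the lowest (-0.19) and the highest (0.20) control. Against the mean of the other 3 controls the extracts of set 10 averaged 0.77 (0.32 to 1.02), which argues against its low control as the whole cause. Those of set 13 averaged 0.94 (0.45 to 1.34), but its control was the highest, so this exchange could only raise them and decides nothing. Growth that goes with the estrogen-like response was tested by the relation of the 2 list means across the 20 compounds within sets: Pearson's r was 0.953 and Spearman's rho 0.929 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give; 1 relation was computed), and r was 0.930 without genistein and nonylphenol. Some extracts were above the highest control on the cell cycle list with little or no rise of the estrogen-induced list: PCB126 (0.39 with 0.02, and 0.24 with -0.0009), tetrabromobisphenol A 10 uM (0.35 with 0.09) and TCDD 1 nM (0.25 with 0.06). So were benzo(a)pyrene 1 uM (0.34 with -0.06), dimethyl-benz(a)anthracene 1 uM (0.26 with 0.06) and p,p'-DDT 1 uM (0.25 with 0.11). The values are consistent with growth under estrogen-like compounds, a hypothesis found and tested on the same data, but it does not cover these extracts.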

How the results depend on the processing

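Alternatives with scan days, slides, the worst closing loop, the array with most outlier spots or single times left out were chosen only after the data were seen. No paired analysis was possible because no concentration and time had more than 1 extract and replicate numbers do not link groups; the related compounds were instead matched by concentration and time. Over 40 results and 757 alternatives other than leaving out a concentration, 697 were kept, and of 219 that left one out, 208 were. A list result was kept when its direction and side of the threshold stayed. A count was kept when it stayed within a fixed ratio of the main count, and the androgen value when its direction stayed and it moved by no more than its SD. Counts could thus shift and be kept: 17beta-estradiol at 4 h gave 107 higher and 81 lower with median centring, against 176 and 78. All 40 results were kept with no dim filter, a dye term per campaign, no dye term, a trended and robust prior, the mean of all probes, without the array with most outlier spots, and with slide as a random block. The estimated correlation was not run for the androgen list of 1 gene, the concentration trend was not run with other controls or the spread of 1 time, nor the pairs with the latter. Signals were well above background in at least 82.1% of spots per array and channel, which does not show how many genes dimness limits. Some genes with large changes were dim in the control. In the solvent control of 17beta-estradiol at 48 h the mean log2 brightness was 6.54 for PGR and 6.76 for CXCL12. The normexp offset was added to all signals and can make the changes of such dim genes smaller. By how much was not tested. A lone extract left after leaving one out is assumed to vary like the other groups. For the changes that follow the cause was not tested.

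Controls taken as 1 group gave 35, 593 and 1186 genes for 17beta-estradiol at 1 h, at 4 h and for 48 minus 4 h, 17495 for the sum over 19 compounds, and benzo(a)pyrene minus dimethyl-benz(a)anthracene passed (0.17). The other sets' controls gave 67, 630, 1088 and 18188, and 0.18 for that pair, past the threshold. Repeated names as 2 extracts gave 8, 461, 1041 and 14184, 2 compounds at 1 h, and 0.0111 for p,p'-DDT minus methoxychlor, reversed. The spread of 48 h alone gave 3257 for the sum and 348 for the 4 ligands. Median centring gave 406 for 48 minus 4 h and turned PCB126 (-0.0112). The reversed values with Agilent's log ratios were -0.0743 for PCB126 and 0.0337 for p,p'-DDT minus methoxychlor, with 2 compounds at 1 h and 0.23 for benzo(a)pyrene minus dimethyl-benz(a)anthracene, past the threshold. The series matrix gave -0.0770 for PCB126 and 0.0621 for p,p'-DDT minus methoxychlor, both reversed, and 2 compounds at 1 h. Separate channels ended the call of diethylhexylphthalate (0.29) and turned tetrabromobisphenol A (-0.00081) and p,p'-DDT minus methoxychlor (0.0255). The 50% filter left 1 compound at 1 h.

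The estimated correlation left 0 compounds at 1 h and 10 at 4 h, and it ended, at the same means, several calls. At 48 h these were calls of the estrogen-induced list with 17beta-estradiol (1.20), endosulfan (0.44), p,p'-DDT (0.52), toxaphene (0.44), nonylphenol (1.27), methoxychlor (0.89), bisphenol A (0.24), genistein (1.28), diethylhexylphthalate (0.37), testosterone (1.03), lindane (0.82), dicyclohexylphthalate (0.97), kepone (1.02) and thyroid hormone (0.73). They were also calls of the aryl hydrocarbon receptor list with benzo(a)pyrene (1.117) and dimethyl-benz(a)anthracene (0.31), and of the pairs 17beta-estradiol minus testosterone (0.25) and diethylhexylphthalate minus dicyclohexylphthalate (-0.26).

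Without the worst closing loop (SD 0.34 against a median of 0.13) benzo(a)pyrene turned (-0.0541). A dye term per scan day brought dimethyl-benz(a)anthracene (0.18) and TCDD (0.27) past the threshold. P,p'-DDT minus methoxychlor turned without 1 h (0.0298) and without 4 h (0.0331). Without 4 h 17beta-estradiol minus testosterone lost its call (0.13) and benzo(a)pyrene minus dimethyl-benz(a)anthracene turned (-0.0304). Without 48 h the latter passed (0.28) and diethylhexylphthalate minus dicyclohexylphthalate did not (-0.15). Leaving out each concentration gave 0 to 1 genes for the concentration trend, 0 to 5 compounds at 1 h, -0.0601 to 0.49 for benzo(a)pyrene, -0.0194 to 0.50 for bisphenol A, -0.00091 to 0.0208 for PCB126, 0.0608 to 0.44 for TCDD, 0.0606 to 0.81 for toxaphene and 0.0766 to 0.54 for the aryl hydrocarbon receptor list with dimethyl-benz(a)anthracene.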

Other observations

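The tests of the solvent control and of thyroid hormone itself, of spot brightness and of the rise with concentration, and the simulations of unchanged extracts, were chosen only after the result was seen; those of a wrong label, the scan day, p,p'-DDT itself, chance splits and ALDH1A3 were written before.

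Benzo(a)pyrene, whose metabolites damage DNA, raised p53 targets at 48 h: 13 of 15 rose over all genes and 14 adjusted over the list alone, by 1.28 on average (1.106 to 1.46; adjusted p = 4.9e-25; adjusted p = 6.7e-10 with an estimated correlation). The list was at 1.502 at 1 uM and 1.06 at 10 uM, with FDXR (2.17), DDB2 (2.09), the nuclease AEN (2.08), the death receptor FAS (1.89), CDKN1A (1.64) and BAX (1.504) leading. Of the NRF2 targets 6 of 10 rose, and 8 adjusted over the list alone, by 0.72 on average (0.52 to 0.92; adjusted p = 8.9e-09; adjusted p = 2.2e-04 with an estimated correlation). TXNRD1 (1.34), GCLM (1.19), ME1 (1.03) and G6PD (0.98) were among them. The thyroid list passed (0.52, adjusted p = 0.0021) through ME1 and BCL3 (0.69), a malic enzyme and an NF-kappaB cofactor. The endoplasmic reticulum stress list was lower (-0.33; adjusted p = 0.020 with an estimated correlation) with ATF4 (-0.69) and HERPUD1 (-0.45) falling. With dimethyl-benz(a)anthracene the p53 list averaged 0.15, with 1 gene passing (adjusted p = 0.28 with an estimated correlation), and was at -0.01 at 1 uM and 0.31 at 5 uM.

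At 4 h the NRF2 target list was lower with 12 of 20 compounds, while the 4 controls themselves ranged from -0.21 (set 10) to 0.14 (set 11) about their mean. The set 13 control, shared by dicyclohexylphthalate, lindane and kepone, lay at -0.01, so their falls do not rest on a deviating control. That of set 11, shared by p,p'-DDT, nonylphenol and toxaphene, was the highest. That of set 12, shared by genistein and testosterone, lay at 0.07. Falls against the controls of sets 11 and 12 would be smaller against the mean of all 4. Whether these calls would then hold was not tested. With an estimated correlation 8 of these calls held: p,p'-DDT (-0.33), dicyclohexylphthalate (-0.28), genistein (-0.27), nonylphenol (-0.25), lindane (-0.24), kepone (-0.23), toxaphene (-0.22) and testosterone (-0.19). HMOX1 fell with dicyclohexylphthalate (-1.36), p,p'-DDT (-1.28), genistein (-1.27), nonylphenol (-1.22), lindane (-1.15), 17beta-estradiol (-0.91), kepone (-0.90) and methoxychlor (-0.88).

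Thyroid hormone at 150 nM and 48 h carried the 17beta-estradiol profile, with the estrogen-induced list at 1.133. Against the controls of the other 3 sets it was 1.085, and the highest control was at 0.05, which argues against an offset of the set 13 control. A wrong label or swap cannot be told apart from a response to the hormone. Over 3039 genes that 17beta-estradiol did not change, thyroid hormone 15 nM ranked 11 of 11 in correlation with it (r = 0.06 across genes) and dicyclohexylphthalate 10 uM first (0.83). All share the set 13 control, and simulations of unchanged extracts gave means of 0.332 and 0.335 for these 2. In only 1 of 10 extracts of other compounds did the sister concentration come first. A response to thyroid hormone itself may be present, since 15 nM gave 0.324 (adjusted p = 0.0039 with that extract alone), but that call was lost with an estimated correlation (adjusted p = 0.39), and both stay open.

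At 1 h p,p'-DDT 5 uM and methoxychlor 5 uM differed in 1079 genes, 470 higher with p,p'-DDT and 609 with methoxychlor, and p,p'-DDT 5 uM alone changed 155 genes against 6 for methoxychlor 5 uM. A dye bias between scan days was tested with a dye term per scan day, which left 899 genes and argues against it as the cause. A bias with brightness was tested by the Spearman correlation of the difference with mean brightness across genes (-0.0307). The loess step had already removed trends with brightness within each array, so a small value was set by the processing and decides nothing. The difference did not belong to these extracts alone: across genes the changes of other extracts correlated with it, nonylphenol 10 uM (181 genes changed) at -0.696 and PCB126 2 uM, of another set and loop, at -0.593. In 100 simulations of unchanged extracts in the same array design the means were -0.126 and -0.0004 (down to -0.19 and -0.06). Extracts that share a loop with either of the 2 are not given, since array error alone ties them to the difference. Whether it is a response to p,p'-DDT cannot be told apart from a fault of that extract or from a cause that several extracts share. The source name of the 5 uM extract reads dtt, and it was taken as p,p'-DDT from its compound label. At 1 h, 1 uM (against the controls of sets 10 and 12) and 5 uM (against those of sets 11 and 13) correlated at -0.255 across genes. The 2 extracts share a loop and this correlation was not simulated for unchanged extracts, so it cannot decide. At 48 h, 1 uM gave 0.11 on the estrogen-induced list where 5 uM gave 0.92, so a weak lower concentration does not exclude a response.

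For the 779 genes of the 4 aryl hydrocarbon receptor ligands, 45 choices of which extract in each set is called the control were compared over genes with all extracts. The real choice called 775 genes and was the only 1 to reach that number, the highest other calling 579. With 45 choices the lowest share attainable is 1 of 45, so this argues against chance but does not exclude it. The estrogen-induced list was higher at the highest than at the lowest concentration for 16 of 20 compounds (exact two-sided sign test, p = 0.0118). The fall of the aryl hydrocarbon receptor list with 17beta-estradiol at 48 h did not rest on ALDH1A3 alone: without it the 5 other genes averaged -0.71 (-1.04 to -0.39).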
